A study of Homo sapiens with 12 samples.

How the data were processed

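Tumors of the human glioblastoma line U87 MG were grown in the brains of 6 mice, of which 3 received irradiation of the opposite hemisphere in 3 fractions of 5 Gy and 3 served as unirradiated controls. Per the labels' protocols, the mice were followed until weight loss or neurological signs, brains were frozen, sectioned, fixed in acetone and stained, and the tumor core and periphery were separated by laser capture microdissection. Total RNA was extracted with Trizol, and biotinylated cRNA was hybridized to an Affymetrix array with 1 colour. How the border between core and periphery was drawn, and the survival time and hybridization batch of each array, are not given in the sources used here.

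The deposited values are log2 expression levels per probe set, made with RMA (background correction, quantile normalization and summarization of probes) per the submitters' processing notes, which give no version. RMA compresses small differences of dim genes toward the background and forces all arrays to the same distribution, so that a change in the total amount of RNA cannot be seen. The 12 arrays had the same quantiles within 0.00190, with quartiles of 4.70 and 6.11, so the values were used as deposited, with no further normalization. The identifiers are gene identifiers in the style of redefined probe sets with 1 probe set per gene. The platform annotation named 23934 of the 24733 probe sets by 1 gene symbol, 0 by several and 799 by none. For the 3 symbols shared by more than 1 probe set, the probe set with the highest mean was kept, which left 23931 genes, with no filter on dim genes. The unnamed probe sets were tested as an alternative, and 0 of the 799 passed in any comparison. For names and for gene neighbours, 23893 gene identifiers were found in a table of the GRCh38.p14 assembly, of which no coordinates are given. All 12 columns of values were assigned to samples, and 0 were left unused. No pair of arrays was a duplicate: the smallest SD of the difference between a pair was 0.196.

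The arrays were fitted together with limma 3.58.1 in R 4.3.3, as 4 group means sharing 1 estimate of the spread, with the mouse as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.222) and moderated statistics from eBayes (8 residual and 1.15 prior degrees of freedom). All tests were two-sided. The 4 comparisons were irradiated minus control in the core, irradiated minus control in the periphery, the difference of those differences (periphery minus core), and periphery minus core over both treatments. Within each, p-values were adjusted over the genes tested by the method of Benjamini and Hochberg, with a threshold of 0.05. An exact test of 3 against 3 arrays cannot go below p = 0.1, so single groups were not tested by permutation. Labels name the mouse of each array, so the core and the periphery of a mouse are a pair. Their deviations from the group means correlated at r = 0.300, 0.662 and 0.670 in control replicates 3, 2 and 1 and at r = 0.377, 0.372 and 0.377 in irradiated replicates 3, 2 and 1. The 3 mice per group are the replicates. The p-value of a single gene rests on 1 moderated spread, estimated over all 12 arrays, and on the consensus correlation shared by all genes. A gene's own spread between mice, and that of its differences within mice, are thus not estimated separately. Fitting each compartment alone and taking mouse as a fixed block come closer to these spreads, and both gave 0 genes in the comparisons they cover. List tests that compare a list with other genes, described below, take genes and not mice as their units. Small p-values of those list tests thus do not measure the spread between mice.

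Of the 27 gene lists, 26 cover motility and invasion, integrins and adhesion, extracellular matrix, proteases, mesenchymal transition, the cell cycle, p53 targets, DNA repair, hypoxia and glycolysis, the interferon response, NF-kB and inflammatory cytokines, class I antigen presentation, the unfolded protein and integrated stress response, immediate early genes, heat shock proteins, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, growth factors and receptors, neural stem markers, and markers of host neurons, oligodendrocytes, astrocytes, microglia, endothelium and erythroid cells. 1 more list was tested and counted with them, and is not reported here. The 719 members of the 27 lists were named before the data were examined, as were the design, the comparisons, the rule for naming genes and the processing alternatives. Of them 660 were measured, at least 70% of each list. The remaining members were not analysed here. Each list was tested with limma's cameraPR on the moderated statistics, with a preset correlation between genes of 0.01, adjusted over the 27 lists within a comparison. The same test with the correlation of each list estimated from the residuals, and fry, which tests whether a list moves one way without comparing it with other genes, were alternatives. Genes within a list vary together, and a preset correlation of 0.01 takes little of that into account, so both values are given for the main fit. Fits with a mouse left out, a filter on dim genes or a covariate used the preset correlation only. Members were also adjusted over the list alone. The host lists hold human symbols, while the host is the mouse, so host RNA can reach them only by cross-hybridization. The host brain score of an array is the mean gene-centred value over the 38 measured members of the neuron and oligodendrocyte lists. Of these members, 4 of 23 neuronal and 3 of 15 oligodendrocyte genes had a mean level above 6, and ENO2 is also in the hypoxia list. A call lost with this score as a covariate therefore does not show that host RNA was the cause.

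Genes are named by rule: in each comparison the genes past the threshold, filled up to 10 with those of lowest p, leaving out zinc finger genes, small RNAs, pseudogenes and uncharacterised loci, and of each list up to 4 members past the threshold or else the 2 of lowest p. Others are said to be chosen after their values were seen.

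The fit was tested on simulated data with the real genes, means and spread and 66 or 67 changed genes for each size of change. Of changes of 0.5, 1 and 2 on the log2 scale it recovered 43.3%, 52.2% and 90.9% in the core, 38.8%, 56.7% and 89.4% in the periphery and 58.2%, 79.1% and 98.5% between compartments, over 23931 genes. The false calls in these runs were 5, 7 and 11. All changed genes lay above the median level, and the sizes were changed together in 1 run. The threshold is stricter where fewer genes change, so these shares may overstate the power of the real comparisons. With no change simulated it called 0 genes in the core, 0 in the periphery, 1 for the difference and 0 between compartments, and 0 lists, although simulated genes vary independently and real ones do not. A simulated shift of -0.4 of the p53 list was estimated as -0.395.

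The alternatives were quantile normalization applied again, centring arrays on the median, filters at the 25th and 50th percentile of the mean level, the mean of a gene's probe sets, every probe set on its own, an intensity trend with robust spread, array weights, no mouse block, mouse as a fixed block, the replicate number as a block, the host brain score as a covariate, each compartment fitted alone, other thresholds, and each mouse left out in turn. The p53 score was also weighed against other splits of the mice, covariates, neighbouring genes and random lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.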

Results

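Gene expression was measured in tumors of U87 MG, an established human glioblastoma cell line that here carried a luciferase reporter, grown in the brains of immunodeficient NSG mice. The tumor cells were implanted in the caudate putamen, a deep nucleus of the forebrain. Treated mice were then given 3 fractions of 5 Gy to the brain hemisphere that held no tumor, and control mice with tumors were left unirradiated. The core and the periphery of each tumor, called proliferative and invasive in the sample labels, were dissected by laser capture and hybridized separately, so that 6 mice gave 12 arrays in 4 groups of n = 3: core control, core irradiated, periphery control and periphery irradiated. All values are log2 expression levels, with a median of 5.00 on every array and a range from 4.42 to 13.6, and 23931 named genes were tested. The small number of arrays limits the precision: the median standard error of an irradiation difference was 0.0619 on the log2 scale. That median is taken over all genes, dim ones included, and many of the genes named below had larger standard errors.

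Pairs of arrays correlated over genes at r = 0.960 to 0.992, and pairs within a group at r = 0.962 to 0.989. The first principal component held 34.0% of the variance and spread the control arrays more than the irradiated arrays. On it, the core control arrays lay at -37.5 (replicate 3), -34.9 (replicate 2) and 17.9 (replicate 1), while the irradiated arrays of both compartments lay between -1.22 and 19.7. Of the host markers, 6 abundant transcripts chosen after their values were seen, MBP, MOG and MOBP of myelin, C1QA and AIF1 of microglia and HBB of red blood cells, lay between 4.57 and 4.76 on all 12 arrays, below the median of all genes.

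The first comparison asked how the tumor core differed between irradiated and control mice. STK10, a serine/threonine kinase, was lower in the irradiated core, at 7.24 ± 0.10 against 8.56 ± 0.30 in controls (SD, n = 3 each), a 2.49-fold difference. The genes that the tumor suppressor p53 activates fell as a group, with a median log2 difference of -0.42 over 24 measured members (limma, adjusted p = 1.44e-13, and adjusted p = 0.0196 with an estimated correlation). Genes of cell motility and invasion and of inflammatory signalling also had lower medians, of -0.15 and -0.55, and neural stem and progenitor markers had a higher one, of 0.16. These 3 lists passed with the preset correlation and not with an estimated one (adjusted p = 0.184, 0.318 and 0.263).

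At an adjusted p under 0.05, 2 of the 23931 genes passed in the core (limma, Benjamini-Hochberg). STK10 differed by -1.32 ± 0.13 (SE; adjusted p = 0.0315), and ZNF584, a zinc finger gene chosen after its values were seen, by 0.31 ± 0.03 (adjusted p = 0.0315). Both were separated from the controls in all 3 replicates. The next genes did not pass: HSD11B2, the enzyme that inactivates cortisol, differed by 0.43 (adjusted p = 0.0565), HSPA5, the main chaperone of the endoplasmic reticulum, by -0.48 ± 0.06 (adjusted p = 0.114), and RSBN1 by 0.33 (adjusted p = 0.114). APOE, a lipid-carrying apolipoprotein, differed by -0.38 (adjusted p = 0.150). LRRC17, the transcription factor TCF12, CBY1 and SERTAD4 differed by 0.999, 0.40, 0.51 and 2.50, all with an adjusted p of 0.235. At an unadjusted p under 0.05, 1203 genes were higher and 974 lower, where 1197 in all would pass by chance. The values of irradiated and control arrays did not overlap for 13.6% of genes, where chance gives 10%. The differences of STK10 and ZNF584 held with each mouse left out, at -1.49 to -1.21 and 0.29 to 0.33. The count depended on single mice. It was 0 without control replicate 3, control replicate 2, irradiated replicate 3 or irradiated replicate 2. It was 3 without irradiated replicate 1, with neither STK10 nor ZNF584 among them. It was 126 without control replicate 1, of which 31 were higher and 95 lower. It was also 0 with an intensity trend and robust estimation of the spread, with the core arrays fitted alone, or with the host brain score as a covariate.

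Of the 27 gene lists, 13 passed in the core with the preset correlation, 1 higher and 12 lower, and 1 of them, the p53 targets, held with an estimated correlation. With fry, limma's test of a list by itself, the p53 target list had an adjusted p of 0.0820 in the core. Of its 24 members 22 lay below 0. None passed over all genes, and 8 passed adjusted over the list alone, all of them lower. MDM2, the ubiquitin ligase that degrades p53, differed by -0.99 ± 0.18, and SESN2, a stress-induced regulator of growth signalling, by -0.57 ± 0.10 (SE; adjusted p = 0.00391 over the list alone for both). Among members chosen after their values were seen, the death receptor FAS differed by -0.86 ± 0.23, the cell cycle inhibitor CDKN1A by -0.74 ± 0.25 and the apoptosis effector BAX by -0.38 ± 0.11, and these 3 also passed over the list alone.

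**Figure D1:**
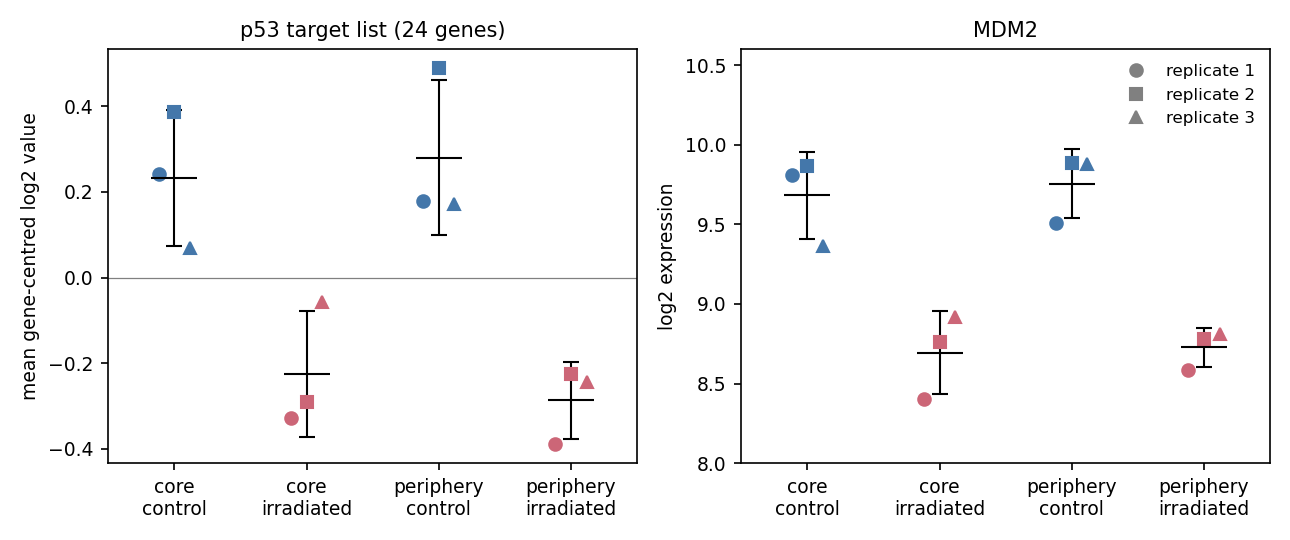
Left, the p53 target score of each array, the mean over 24 genes of the gene-centred log2 value, by group; right, the log2 expression of MDM2. Points are arrays, with the replicate number as the marker, and bars are the mean ± SD (n = 3): the score was 0.23 ± 0.16 and 0.28 ± 0.18 in the control core and periphery and -0.23 ± 0.15 and -0.29 ± 0.09 in the irradiated core and periphery, and MDM2 lay between 8.40 and 8.92 in irradiated and between 9.37 and 9.88 in control tumors.

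Motility and invasion regulators fell in the core (adjusted p = 0.00406, and adjusted p = 0.184 with an estimated correlation), with 31 of 46 members below 0. No member passed over all genes or adjusted over the list alone. PXN, the focal adhesion adaptor paxillin, differed by -0.69 (adjusted p = 0.416) and PLAU, the urokinase that activates plasminogen, by -0.61 (adjusted p = 0.416). This call was lost without irradiated replicate 2 (adjusted p = 0.0873). Proteases and protease inhibitors had a median of -0.18 (adjusted p = 0.0192, and adjusted p = 0.263 with an estimated correlation), while their members of lowest p, the metalloprotease MMP16 and the serine protease HTRA1, lay higher, by 1.10 and 1.01. That list lost its call without control replicate 3, control replicate 2 or irradiated replicate 1 (adjusted p = 0.144, 0.105 and 0.108), and among genes above the median level (adjusted p = 0.0521). No protease passed over all genes or adjusted over the list alone.

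Inflammatory genes of the NF-kB pathway fell in the core with 22 of 24 members below 0 (adjusted p = 2.36e-05, and adjusted p = 0.318 with an estimated correlation). Among them the interleukin receptor IL1R1 differed by -1.02 and the cytokine LIF by -1.01. The fall came from 2 control mice: the mean gene-centred value of the list was 1.35, 0.63 and -0.36 in the cores of control replicates 3, 2 and 1 and 0.16, -0.27 and -0.40 in those of irradiated replicates 3, 2 and 1. The microglia list was also high in the same control mice, at 0.27, 0.19 and -0.10. Only 3 of its 20 members had a mean level above 6, and C1QA and AIF1 did not differ so, at 4.74, 4.72 and 4.76 and at 4.67, 4.66 and 4.64. That score therefore does not show more microglia in these mice. ENPP2, a member of the host brain score chosen after its values were seen, was high in these 2 control mice too, at 8.80, 8.14 and 5.21 in the control cores. The score thus does not separate host RNA from differences between tumors. With the score as a covariate the median of the NF-kB list went from -0.55 to -0.10. Its call was then lost (adjusted p = 0.216). Genes of the unfolded protein and integrated stress response fell by a median of 0.14 on the log2 scale (adjusted p = 2.12e-04, and adjusted p = 0.246 with an estimated correlation), and 1 of 24 members, HSPA5, passed adjusted over the list alone. Class I antigen presentation had a median of -0.19 (adjusted p = 0.00102, and adjusted p = 0.440 with an estimated correlation), with B2M, the light chain of the class I complex, at -0.28. Its call was lost without irradiated replicate 3 (adjusted p = 0.169). Immediate early genes had a median of -0.16 (adjusted p = 4.59e-04, and adjusted p = 0.318 with an estimated correlation), lost without irradiated replicate 2 (adjusted p = 0.0803). For oxidative phosphorylation the median was -0.14 (adjusted p = 0.00133, and adjusted p = 0.440 with an estimated correlation). CYC1, cytochrome c1 of the respiratory chain, at -0.83 was the 1 member of that list past the threshold adjusted over the list alone, and the call was lost without irradiated replicate 3 (adjusted p = 0.580). Heat shock proteins had a median of -0.17 (adjusted p = 0.0458, and adjusted p = 0.440 with an estimated correlation), lost without control replicates 3 or 2 or irradiated replicates 3 or 2 (adjusted p = 0.126, 0.185, 0.198 and 0.0785) and among genes above the median level (adjusted p = 0.0695). Cholesterol synthesis genes also had a median of -0.17 (adjusted p = 0.0405, and adjusted p = 0.598 with an estimated correlation), lost without control replicates 3 or 1 or irradiated replicates 3 or 2 (adjusted p = 0.176, 0.155, 0.358 and 0.195) and among genes above the median level (adjusted p = 0.0521). Neural stem and progenitor markers rose (adjusted p = 0.00402, and adjusted p = 0.263 with an estimated correlation), with the neural transcription factor POU3F2 at 0.35 past the threshold adjusted over the list alone, and lost the call without control replicate 3 (adjusted p = 0.0527) or irradiated replicate 3 (adjusted p = 0.0781). Their mean gene-centred value was -0.48, -0.22 and 0.23 in the cores of control replicates 3, 2 and 1. In those of irradiated replicates 3, 2 and 1 it was 0.24, 0.06 and 0.30, so control replicate 1 lay among them. In the lists of NF-kB genes, antigen presentation, immediate early genes, heat shock proteins and cholesterol synthesis no member passed adjusted over the list alone, and over all genes no member of any list passed.

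The remaining lists did not pass in the core. Their medians were -0.09 for extracellular matrix, -0.04 for mesenchymal transition, 0.02 for integrins and adhesion molecules, -0.05 for the cell cycle, 0.03 for DNA repair, -0.11 for hypoxia and glycolysis, 0.02 for the interferon response, 0.00 for ribosomal proteins and -0.08 for growth factors and their receptors. Some of them passed with a mouse left out. The cell cycle list lay at -0.33 without control replicate 2 (adjusted p = 3.14e-06) and at -0.21 without irradiated replicate 1 (adjusted p = 0.00607). The hypoxia list lay at -0.77 without control replicate 1 (adjusted p = 1.45e-04) and at -0.54 without irradiated replicate 3 (adjusted p = 0.00250). Other mice left out turned the sign, and these fits did not pass. The cell cycle list lay at 0.05, 0.12 and 0.06 without control replicate 3, control replicate 1 or irradiated replicate 3. The hypoxia list lay at 0.10, 0.06 and 0.09 without control replicate 3, control replicate 2 or irradiated replicate 2. DNA repair lay at 0.15 without control replicate 1 (adjusted p = 0.0457). Extracellular matrix and mesenchymal transition lay at -0.27 and -0.08 without irradiated replicate 3 (adjusted p = 0.0203 and 0.00475). NBN, a sensor of DNA double-strand breaks, at 0.50 was the 1 member of these lists past the threshold adjusted over the list alone. The host neuron list passed with a median of -0.03 (adjusted p = 0.0405, and adjusted p = 0.440 with an estimated correlation), except without control replicate 1 or irradiated replicates 2 or 1 (adjusted p = 0.255, 0.164 and 0.1005) or among genes above the median level (adjusted p = 0.181). Its 1 member past the threshold adjusted over the list alone was SNAP25, a synaptic vesicle fusion protein, at -1.57 ± 0.33. The host oligodendrocyte, astrocyte, microglia, endothelium and erythroid lists had medians of 0.01, 0.03, -0.00, -0.03 and 0.02 and did not pass. Microglia passed without control replicate 1, at -0.01 (adjusted p = 0.0291). Among genes above the median level they lay at -0.78 and passed (adjusted p = 0.0116). The host brain score of the core arrays was 0.0833, 0.0874 and -0.0609 in control replicates 3, 2 and 1 and -0.0502, -0.0641 and -0.126 in irradiated replicates 3, 2 and 1. With that score as a covariate, 8 lists passed in the core, 6 of them among the 13. The hypoxia list then had a median of 0.36 (adjusted p = 0.00629) in place of -0.11. The cell cycle list had one of -0.38 (adjusted p = 4.34e-07). The score also ended the calls of antigen presentation (-0.06, adjusted p = 0.441), heat shock proteins (-0.04, adjusted p = 0.910) and neural stem markers (0.05, adjusted p = 0.216). The same holds for proteases (-0.12, adjusted p = 0.216) and oxidative phosphorylation (-0.07, adjusted p = 0.185). The host neuron list is part of the score, so its loss says nothing. Without irradiated replicate 2, too, 8 lists passed.

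The second comparison asked the same of the tumor periphery. The p53 targets fell again as a group, by a median of 0.51 on the log2 scale, with 24 of 24 members below 0 (adjusted p = 5.37e-24, and adjusted p = 1.79e-04 with an estimated correlation). Genes of hypoxia and glycolysis had a median of -0.50 and those of the cell cycle a median of 0.29. The median of motility and invasion regulators was -0.06. MDM2 lay at 8.73 ± 0.12 in the irradiated and 9.76 ± 0.22 in the control periphery (SD, n = 3 each), a 2.04-fold difference.

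No gene passed in the periphery (limma, lowest adjusted p = 0.440), where 744 genes were higher and 616 lower at an unadjusted p under 0.05 and 1197 in all would pass by chance. The other limma settings, with an intensity trend, with array weights or on the periphery arrays alone, also gave 0. Without control replicate 1 the count was 6, and without irradiated replicate 3 it was 1. The values did not overlap for 11.4% of genes, where chance gives 10%. The genes of lowest p, none of which passed, were HSPA5 at -0.48, GGT7, of the gamma-glutamyltransferase family, at -0.45, APOE at -0.33 and STK10 at -0.83 (adjusted p = 0.440 for these 4), OLFM1 at -0.19 (adjusted p = 0.477), MDM2 at -1.03 ± 0.18, the histone methyltransferase SETD2 at 0.36, KIRREL1 at -0.50, the interleukin receptor IL11RA at -0.17 and the DNA repair gene PALB2 at 0.38 (adjusted p = 0.507 for these 5).

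Of the 27 lists, 14 passed in the periphery with the preset correlation, 3 higher and 11 lower, and again the p53 targets were the 1 list that held with an estimated correlation. With fry it had an adjusted p of 0.0269. None of its members passed over all genes, and 13 of 24 passed adjusted over the list alone, all lower, MDM2 and SESN2 (-0.52) among them. Further members, chosen after their values were seen, were ZMAT3, an RNA-binding p53 target, at -1.28 ± 0.25, the DNA damage binding protein DDB2 at -1.33 ± 0.38, CDKN1A at -0.77 ± 0.25 and BAX at -0.51 ± 0.11. Motility and invasion regulators had an adjusted p of 7.22e-04 (adjusted p = 0.0543 with an estimated correlation), with 33 of 46 members below 0 and 10 lower at an unadjusted p under 0.05. PLAU differed by -0.67 and the semaphorin receptor PLXNB2 by -0.72, and no member passed over all genes or adjusted over the list alone. The unfolded protein and integrated stress response had a median of -0.13 (adjusted p = 2.05e-05, and adjusted p = 0.109 with an estimated correlation), with 1 member, HSPA5, past the threshold adjusted over the list alone. Immediate early genes had a median of -0.22 (adjusted p = 3.21e-05, and adjusted p = 0.195 with an estimated correlation), and 2 members passed adjusted over the list alone, IER2 at -0.16 and FOSB at -0.12. Inflammatory NF-kB genes had a median of -0.32 (adjusted p = 7.22e-04, and adjusted p = 0.478 with an estimated correlation), with IL1R1 at -0.84 and the NF-kB inhibitor NFKBIA at -1.23. As in the core, control replicates 3 and 2 carried this fall: the mean gene-centred value was 0.17, 0.33 and -0.33 in control replicates 3, 2 and 1. It was -0.48, -0.30 and -0.50 in irradiated replicates 3, 2 and 1, with control replicate 1 inside their range. These 5 lists kept their calls with each mouse left out.

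The other 9 calls in the periphery were each lost without at least 1 mouse, and none of the members of these lists passed over all genes or adjusted over the list alone. Hypoxia and glycolysis genes had an adjusted p of 1.55e-04 (adjusted p = 0.643 with an estimated correlation), lost without control replicate 2 (adjusted p = 0.0719). Of their 29 members 27 lay below 0, with the stress-induced inhibitor of growth signalling DDIT4 at -1.89 and the carbonic anhydrase CA12 at -2.27. Cell cycle genes rose with 31 of 36 members above 0 (adjusted p = 0.00368, and adjusted p = 0.793 with an estimated correlation), with the cyclin CCNE2 at 0.88 and NUSAP1, of the mitotic spindle, at 0.48. Their call was lost without control replicate 2 (adjusted p = 0.607) or irradiated replicate 3 (adjusted p = 0.420). DNA repair genes had a median of 0.14 (adjusted p = 0.00368, and adjusted p = 0.494 with an estimated correlation), lost without the same mice (adjusted p = 0.0893 and 0.405). Extracellular matrix genes had a median of -0.16 (adjusted p = 0.00368, and adjusted p = 0.419 with an estimated correlation), with the fibrillin FBN1 at -0.58. They lost the call without control replicate 3 (adjusted p = 0.104), and without irradiated replicate 1 their median was 0.02 (adjusted p = 0.397). Mesenchymal transition genes had a median of -0.19 (adjusted p = 0.00369, and adjusted p = 0.165 with an estimated correlation) and growth factors and receptors a median of -0.05 (adjusted p = 0.00611, and adjusted p = 0.165 with an estimated correlation), both lost without control replicate 3 (adjusted p = 0.0694 and 0.0622). Proteases had a median of -0.12 (adjusted p = 0.0256, and adjusted p = 0.238 with an estimated correlation), lost without control replicates 3 or 2 or irradiated replicates 2 or 1 (adjusted p = 0.120, 0.0729, 0.0626 and 0.139). Cholesterol synthesis genes had a median of 0.12 (adjusted p = 0.0150, and adjusted p = 0.628 with an estimated correlation), lost without control replicates 2 or 1 or irradiated replicates 3 or 1 (adjusted p = 0.0581, 0.466, 0.405 and 0.0638). The host neuron list had a median of -0.03 (adjusted p = 0.0470, and adjusted p = 0.478 with an estimated correlation), lost without control replicates 2 or 1 or irradiated replicates 3, 2 or 1 (adjusted p = 0.698, 0.219, 0.140, 0.0885 and 0.144). Among genes above the median level it was lost too, at -0.28 (adjusted p = 0.154). With the host brain score as a covariate 5 lists passed in the periphery, all of them among the 14, and the medians of the cell cycle, hypoxia and NF-kB lists were -0.02, 0.03 and 0.02. The score also ended the calls of DNA repair (0.02, adjusted p = 0.617), proteases (-0.01, adjusted p = 0.453), mesenchymal transition (-0.16, adjusted p = 0.0727), growth factors and receptors (-0.07, adjusted p = 0.116) and cholesterol synthesis (0.16, adjusted p = 0.305). The host neuron call ended too, by construction. Without control replicate 2, 8 lists passed.

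Lists that did not pass in the periphery had medians of -0.02 for integrins, 0.02 for the interferon response, -0.07 for antigen presentation, -0.05 for heat shock proteins, 0.06 for oxidative phosphorylation, 0.02 for ribosomal proteins and 0.01 for neural stem markers. Antigen presentation passed without control replicate 1 at -0.15 (adjusted p = 0.0128) and without irradiated replicate 2 at -0.12 (adjusted p = 0.00269). Heat shock proteins passed without control replicate 1 at -0.15 (adjusted p = 0.0192). The host oligodendrocyte, astrocyte, microglia, endothelium and erythroid lists lay at 0.02, 0.03, -0.01, 0.00 and 0.02. No member of these lists passed over all genes or adjusted over the list alone.

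**Figure D2:**
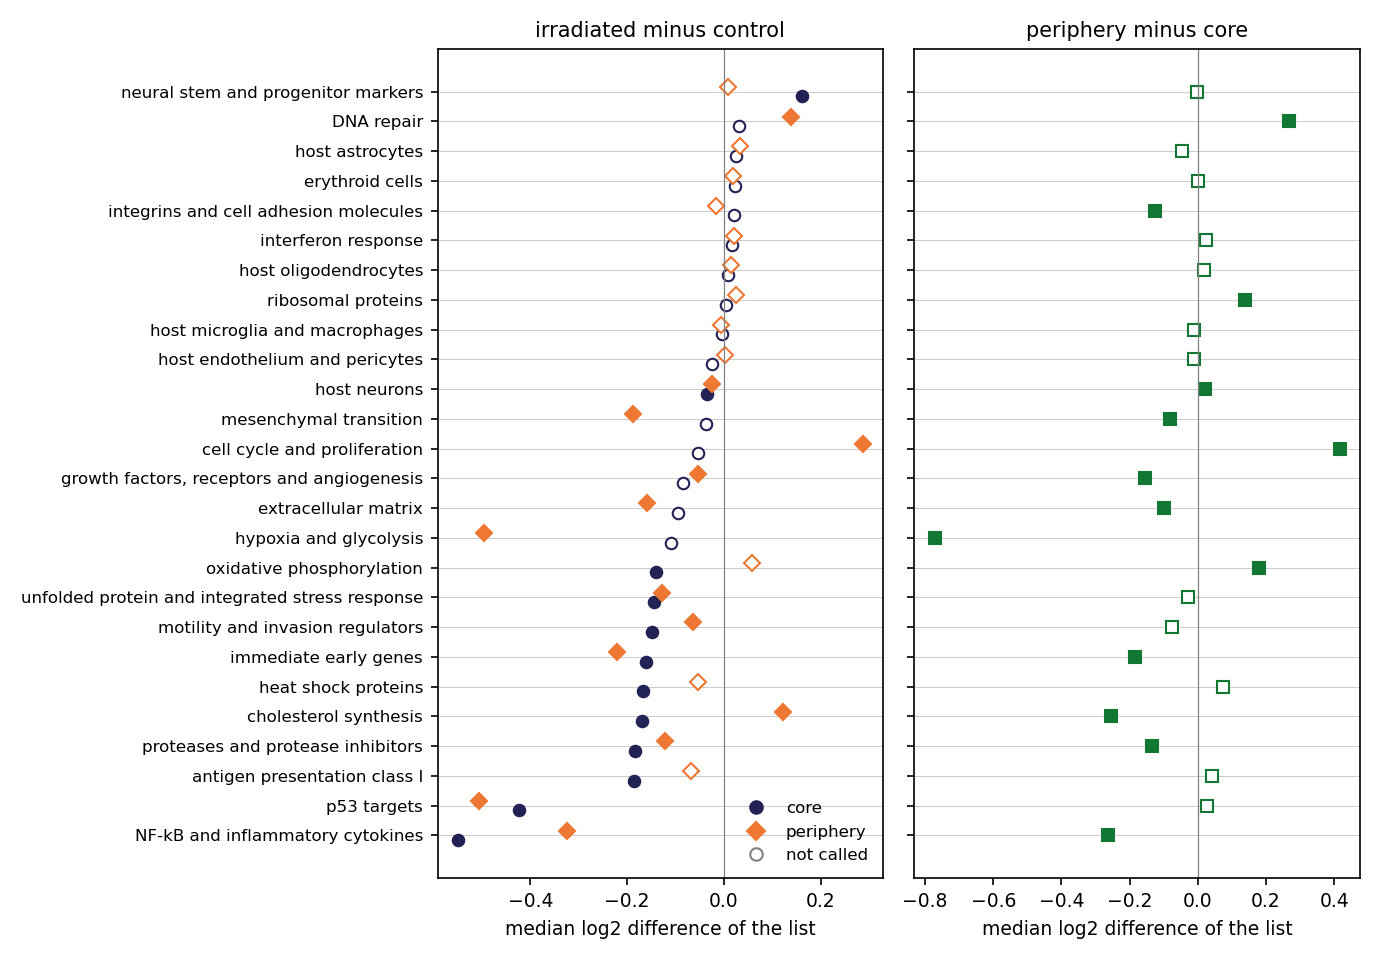
Median log2 difference of each of 26 gene lists, irradiated minus control in the core and in the periphery (left) and periphery minus core (right). Filled symbols are lists that passed at an adjusted p under 0.05 with the preset correlation, open symbols the others: the p53 targets lie at -0.42 and -0.51 on the left and at 0.03 on the right, where hypoxia lies lowest, at -0.77, and the cell cycle highest, at 0.42.

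The third test asked whether the irradiation difference itself differed between the compartments. For the p53 targets it did not pass: the periphery difference minus the core difference had a median of -0.05 (adjusted p = 0.424). Cholesterol synthesis, the cell cycle and oxidative phosphorylation had differences of 0.47, 0.31 and 0.19, higher in the periphery than in the core, and neural stem and progenitor markers a difference of -0.23. These 4 lists passed with the preset correlation and none with an estimated one (adjusted p = 0.800, 0.953, 0.953 and 0.800). The cholesterol genes NSDHL and IDI1 lay at 0.65 and 0.30.

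No gene passed this test (limma, lowest adjusted p = 0.245, 480 higher and 514 lower at an unadjusted p under 0.05, where 1197 in all would pass by chance), and the count was also 0 with the intensity trend, with array weights and with mouse as a fixed block. It was 2 without irradiated replicate 1. The genes of lowest p were IL11RA at -0.33 ± 0.04, HSD11B2 at -0.38, PPFIA1 at 0.44, MED10, a subunit of the transcriptional Mediator complex, at 0.76, GGACT at 0.14, LYSMD4 at -0.15, WDR82 at -0.38, CCDC170 at 0.14, LRIF1 at 0.54 and the transcription factor TEF at -0.20. The 4 lists passed with the preset correlation (adjusted p = 6.06e-05, 3.99e-04, 1.11e-04 and 0.00907 in the order given). Without irradiated replicate 3 none of the 4 passed (adjusted p = 0.185, 0.882, 0.126 and 0.126). The cholesterol and cell cycle calls were also lost without control replicate 1 (adjusted p = 0.0506 and 0.374), and the neural stem call without control replicate 2 (adjusted p = 0.115). No list member passed over all genes, and adjusted over the list alone 1 did, the angiogenic growth factor PGF at -0.47. The other lists reported here did not pass, with medians between -0.30 for hypoxia and 0.13 for NF-kB genes. The hypoxia list passed without control replicate 3 at -0.77 (adjusted p = 5.40e-06) and without irradiated replicate 2 at -0.51 (adjusted p = 1.89e-04). It also passed with the host brain score at -0.35 (adjusted p = 0.00204) and among genes above the median level (adjusted p = 0.0176). Without control replicate 1 or irradiated replicate 3 it lay at 0.02 and 0.04 and did not pass. NF-kB genes passed without control replicate 1 at 0.26 (adjusted p = 0.0133). Growth factors and receptors passed without irradiated replicate 2 at -0.11 (adjusted p = 0.00428).

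The fourth comparison set the periphery against the core within mice, over both treatments. Hypoxia and glycolysis genes were lower in the periphery, by a median log2 difference of -0.77 with 29 of 29 members below 0, and cell cycle genes were higher, by a median of 0.42 with 36 of 36 members above 0. Both passed with the preset correlation and neither with an estimated one (adjusted p = 0.268 for each). Both scores went the other way in control replicate 1. Of the 32 exchanges of core and periphery within mice, 2 gave a hypoxia median as far from 0, and 2 a cell cycle median as far, the real one included. Genes of DNA repair, oxidative phosphorylation and ribosomes also lay higher, by 0.27, 0.18 and 0.14. These did not hold with an estimated correlation either (adjusted p = 0.0890, 0.223 and 0.0890). PSMA7, a subunit of the proteasome core, was 1.37-fold higher in the periphery and FOXK1, a forkhead transcription factor, 1.26-fold lower, each in the same direction in 6 of 6 mice. The difference was widest for the collagenase MMP13 among the list members named here, 6.27-fold lower in the periphery and lower in 6 of 6 mice. Its level in the irradiated periphery, 4.94, lay below the median of all genes, where RMA compresses differences, so the size of this fold is uncertain.

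At an adjusted p under 0.05, 2 genes passed between compartments (limma, Benjamini-Hochberg), PSMA7 at 0.46 ± 0.04 (SE; adjusted p = 0.0229) and FOXK1 at -0.33 ± 0.03 (adjusted p = 0.0372). The next 8 did not pass, at an adjusted p of 0.0806: the arginine methyltransferase PRMT6 at 0.32, LRRC17 at 0.73, ADSL, of purine synthesis, at 0.31, TCF12 at 0.29, HSD11B2 at -0.22, DDHD2 at -0.35, the histone deacetylase HDAC7 at -0.23 and the co-chaperone DNAJC7 at 0.37. At an unadjusted p under 0.05, 1408 genes were higher and 1145 lower, where 1197 in all would pass by chance. For 6.52% of genes all 6 mice differed in the same direction, where chance gives 3.125%. The count of 2 was 0 without control replicate 3, 2 or 1 or irradiated replicate 2 or 1, and 3 without irradiated replicate 3, PSMA7 among them and FOXK1 not. It was 0 with mouse as a fixed block, with mouse left out of the model or with an intensity trend, 12 with array weights, 7 with the host brain score and 25 among genes above the median level.

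Of the 27 lists, 14 passed between compartments with the preset correlation, 5 higher and 9 lower in the periphery, and 1, growth factors and their receptors, held with an estimated correlation. That list had a median of -0.15 (adjusted p = 2.66e-05, and adjusted p = 0.0324 with an estimated correlation). None of its members passed over all genes and 4 passed adjusted over the list alone, all lower: the receptor FGFR1 at -0.46, PGF at -0.28, the ephrin EFNA1 at -0.16 and the growth factor FGF2 at -0.91, the last 2 chosen after their values were seen. Hypoxia and glycolysis had an adjusted p of 1.50e-11 (adjusted p = 0.268 with an estimated correlation), with the mitochondrial receptor BNIP3L at -0.43 and the glycolytic regulator PFKFB3 at -1.14. The cell cycle list had an adjusted p of 7.01e-11 (adjusted p = 0.268 with an estimated correlation), with the chromatin protein HMGB2 at 0.53 and the cyclin CCNB2 at 0.44. In neither of these 2 lists did a member pass over all genes or adjusted over the list alone. DNA repair had an adjusted p of 8.03e-10 (adjusted p = 0.0890 with an estimated correlation), and adjusted over the list alone 5 of 23 members passed, all higher, among them NBN at 0.31 and the damage checkpoint kinase ATR at 0.27. Oxidative phosphorylation (adjusted p = 8.35e-08, and adjusted p = 0.223 with an estimated correlation) had 29 of 29 members above 0, with COX7C, of cytochrome oxidase, at 0.44, and 0 passed over the list alone. Ribosomal proteins (adjusted p = 7.69e-07, and adjusted p = 0.0890 with an estimated correlation) had 26 of 28 members above 0, and RPL35 at 0.23 passed adjusted over the list alone.

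**Figure D3:**
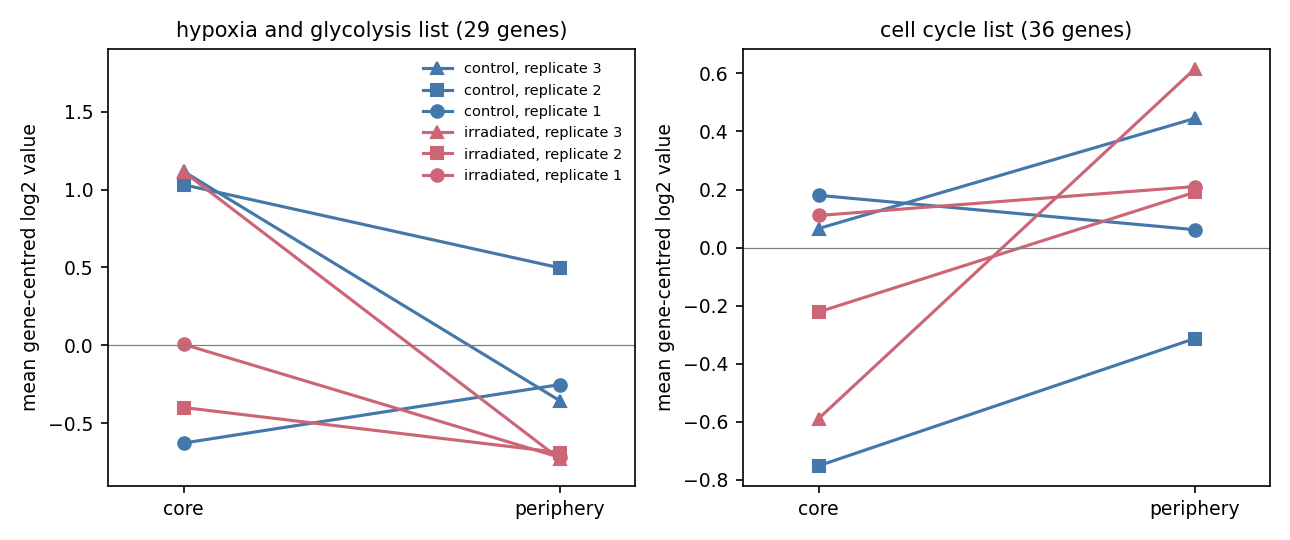
Score of the hypoxia and glycolysis list (left, 29 genes) and of the cell cycle list (right, 36 genes), the mean gene-centred log2 value, in the core and the periphery of each mouse, joined by a line. The median difference over the genes, periphery minus core, was -0.23 to -1.91 for hypoxia in 5 of 6 mice and 0.33 in control replicate 1, and 0.10 to 1.13 for the cell cycle in 5 of 6 mice and -0.15 in control replicate 1.

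Among genes that bear on invasion, extracellular matrix (-0.10, adjusted p = 0.00182, and adjusted p = 0.268 with an estimated correlation), proteases (-0.14, adjusted p = 0.0102, and adjusted p = 0.184 with an estimated correlation) and integrins and adhesion molecules (-0.13, adjusted p = 0.00828, and adjusted p = 0.0705 with an estimated correlation) were lower in the periphery. MMP13 at -2.65 ± 0.40 (adjusted p = 0.0966 over all genes) was the 1 member of these 3 lists past the threshold adjusted over the list alone, and the adhesion molecules VCAM1 and CD9 lay at -1.04 and -0.38. Mesenchymal transition genes had a median of -0.08 (adjusted p = 0.0303, and adjusted p = 0.268 with an estimated correlation), lost without control replicate 2 or irradiated replicates 3 or 1 (adjusted p = 0.107, 0.0688 and 0.0896). Motility and invasion regulators (-0.08, adjusted p = 0.182) did not pass, with CD44, the hyaluronan receptor, at -0.28. Cholesterol synthesis (-0.25, adjusted p = 3.57e-04, and adjusted p = 0.268 with an estimated correlation), NF-kB genes (-0.26, adjusted p = 0.00183, and adjusted p = 0.391 with an estimated correlation) and immediate early genes (-0.18, adjusted p = 0.00663, and adjusted p = 0.387 with an estimated correlation) were also lower, with DHCR7, of cholesterol synthesis, at -0.80 and no member past the threshold adjusted over the list alone. The p53 targets (0.03), heat shock proteins (0.07), antigen presentation (0.04), the interferon response (0.02), the unfolded protein response (-0.03) and neural stem markers (-0.00) did not pass. The interferon response passed without irradiated replicate 2, at 0.05 (adjusted p = 0.0193). No member of any list passed over all genes.

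The lists of host cell markers had medians near 0 between compartments, while single members moved both ways. In a form of fry that lets members go either way, 7 of the 27 lists passed. Of these, 3 were host neurons, oligodendrocytes and astrocytes (adjusted p = 0.0229, 0.0248 and 0.0248). The other 4 were growth factors, DNA repair, ribosomal proteins and proteases (adjusted p = 4.55e-04, 0.0229, 0.0229 and 0.0248). Under irradiation this form of fry passed for 2 lists in the core and the same 2 in the periphery. They were the p53 targets (adjusted p = 0.00843 and 0.00346) and the unfolded protein and integrated stress response (adjusted p = 0.0210 and 0.0233). It passed for 0 lists in the difference between compartments, and it tests no direction. The host neuron list was higher in the periphery by 0.02 (adjusted p = 0.0106, and adjusted p = 0.268 with an estimated correlation), except without control replicates 2 or 1 or irradiated replicate 1 (adjusted p = 0.166, 0.0506 and 0.0525) or among genes above the median level (adjusted p = 0.460). Adjusted over the list alone 3 of its 23 members passed, SYN1 at 0.17, SNAP25 at 0.98 ± 0.20, higher in 6 of 6 mice, and STMN2 at 0.34, the last chosen after its values were seen. Of the members of the host lists, 4 of 23 neuronal, 3 of 15 oligodendrocyte, 7 of 15 astrocyte, 3 of 20 microglial, 5 of 19 endothelial and 2 of 8 erythroid genes had a mean level above 6. The oligodendrocyte, astrocyte, microglia, endothelium and erythroid lists had medians of 0.02, -0.05, -0.01, -0.01 and 0.00 and did not pass with the preset correlation. Among genes above the median level astrocytes lay at -0.20 and passed (adjusted p = 0.0126). GFAP, the intermediate filament of astrocytes that glioma cells also express, differed by -1.23 ± 0.39 and was lower in the periphery of 5 of 6 mice (adjusted p = 0.341). The sign of a list's median, mean and test differed for 2 lists in the core (integrins and oligodendrocytes), 1 in the periphery (endothelium), 4 in the difference between them (unfolded protein response, immediate early genes, astrocytes and neurons) and 2 between compartments (p53 targets and heat shock proteins), and none of these had passed.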

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

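The splits of the mice in this part were chosen as a test only after the result was seen. A set of 4 results drew a closer look because the irradiation difference of a gene list differed between the compartments in the test of that difference itself. As periphery minus core, the median difference was 0.31 for the cell cycle, 0.47 for cholesterol synthesis, 0.19 for oxidative phosphorylation and -0.23 for neural stem and progenitor markers. None of the 4 held with an estimated correlation (adjusted p = 0.953, 0.800, 0.953 and 0.800), and none without irradiated replicate 3 (adjusted p = 0.882, 0.185, 0.126 and 0.126). Of the 10 splits of the 6 mice into 3 and 3, the real split included, 6 gave at least 4 lists, with up to 10 lists in another split, and the splits are too few for a share under 0.05. The real count of genes was 0, which all 10 of 10 splits must reach (up to 1 gene in another split), so that comparison decides nothing. The split that gave 10 lists set control replicate 3 with irradiated replicates 3 and 1 against the other mice. No explanation other than chance was tested for these lists.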

How the results depend on the processing

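All alternatives here were planned before the data were examined, and none was added later, so no test of this part was chosen after the result was seen. Quantile normalization applied again and centring on the median moved nothing, since the arrays already had the same quantiles, and so say nothing about stability. No other cause of a change was tested, and remarks in parentheses such as fewer genes tested only say what a setting alters.

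The p53 targets fell in both compartments under all 12 settings of their test, with medians from -0.52 to -0.35 in the core and from -0.58 to -0.42 in the periphery. Normalizing or centring again, an estimated correlation and fry could not move these medians, so they say nothing about their stability. The p53 list passed in 11 of 12 settings in the core (fry gave 0.0820) and in 12 of 12 in the periphery. With the preset correlation its adjusted p was at most 4.83e-09 in the core and 1.62e-16 in the periphery when a mouse was left out. Fits without a mouse were not tested with an estimated correlation, which with all mice gave an adjusted p of 0.0196 in the core. The lower hypoxia genes of the periphery against the core ranged from -1.003 to -0.49 with a mouse left out, and passed in 6 of 6 such fits.

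Counts of genes were small and moved readily. In the core, 2 genes became 1 with either filter on dim genes or with a 1.5-fold minimum, 0 with the intensity trend, the host brain score or the core arrays alone (fewer arrays estimate the spread), 4 with array weights, 159 at an unadjusted p under 0.01 with a 1.5-fold minimum (86 higher, 73 lower), and between 0 and 126 with a mouse left out. In the periphery, 0 became 49 at that unadjusted threshold (8 higher, 41 lower) and between 0 and 6 with a mouse left out. For the difference between compartments, 0 became 13 and between 0 and 2. Between periphery and core, 2 became 25 above the median level (fewer genes tested), 0 with the trend, 12 with array weights, 7 with the host brain score, 29 at an adjusted p under 0.10, 0 with a 1.5-fold minimum added, 50 at the unadjusted threshold (12 higher, 38 lower) and between 0 and 3 with a mouse left out.

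The mouse pairs core and periphery. With no replicate block for the mouse, 2 genes became 0 between periphery and core, and with mouse as a fixed block also 0 (fewer degrees of freedom). Mice of the same number in the control and irradiated groups share only that number: their deviations correlated at 0.101, 0.0634 and -0.0193 in the core and -0.0931, 0.249 and -0.124 in the periphery for numbers 1, 2 and 3. With the number as a replicate block the count was 0 in the core and 0 between periphery and core. These blocks moved no other count of genes by over 1.5 times.

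Of 13 lists in the core, 1 passed with an estimated correlation, 0 with fry and 8 with the host brain score, and between 8 and 13 with a mouse left out. In the periphery the 14 became 1, 1 and 5, and between 8 and 14. For the difference the 4 became 0 and 0, and between 0 and 6, and between periphery and core the 14 became 1 and 0, and between 12 and 15. With each mouse left out in turn, 3 of the 13, 5 of the 14, 0 of the 4 and 12 of the 14 passed every time. Of the medians that passed before or after, 5 changed sign, and others that passed neither time did so too, such as the core medians of the cell cycle and hypoxia lists with single mice left out. With the host brain score the hypoxia list had 0.36 in the core and 0.026 in the periphery, and in the periphery the cell cycle list had -0.020 and the NF-kB list 0.019. Without irradiated replicate 1 the extracellular matrix list had 0.021 in the periphery, and -0.33 without irradiated replicate 3, the ends of its range. Over the other values of named genes and lists, 4438 and 1102 kept their side of the threshold, 39 and 161 lost it, 23 and 28 gained it, and 0 and 5 changed sign with a call before or after. Only 2 genes in the core and 2 between compartments had passed in the main fit, so most gene values kept their side by not passing. All 39 losses of genes were calls of these genes, 20 in the core and 19 between compartments. The kept values also include normalizing or centring again, which could move nothing. Dim genes, near the background of about 4.42, could not show a decrease.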

Other observations

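Tests chosen only after the result was seen were the splits of the mice and exchanges of compartments for counts of genes and of lists under irradiation and for the count of lists between compartments, the test of dilution by host RNA, and the comparison of chromosome 18 mouse by mouse.

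For 5 genes chosen after their values were seen, the cores of the control tumors differed from each other, and no list was tested for this. CXCL8, a neutrophil-attracting chemokine, lay at 11.28, 9.66 and 4.80 in the core of control replicates 3, 2 and 1, and at 9.46, 4.85 and 5.49 in the core of irradiated replicates 3, 2 and 1. VEGFA, the hypoxia-induced angiogenic factor, lay at 11.11, 10.74 and 8.88 in the control cores in the same order. S100B and GFAP, which mark astrocytes and many gliomas, went the other way, at 5.08, 5.26 and 8.76 and at 5.00, 5.19 and 7.59. In the peripheries of the same control mice the values of these genes lay closer together, and VEGFA was no longer lowest in replicate 1. In the same order, CXCL8 lay there at 6.84, 8.33 and 5.02 and VEGFA at 8.69, 10.12 and 9.30. S100B lay at 5.64, 5.67 and 6.94 and GFAP at 5.11, 5.11 and 5.39. ENPP2, which makes lysophosphatidic acid, lay at 8.80, 8.14 and 5.21 in the control cores and at 8.68, 7.85 and 5.16 in the peripheries of the same mice. Over genes, the irradiation differences of the core and the periphery correlated at r = 0.645, and those of the other 9 splits of the same mice at r = 0.173 to 0.773. The same mice enter both differences, and genes are not independent replicates.

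Counts under irradiation were set against the 10 splits of the 6 mice into 3 and 3, which are too few for a share under 0.05. In the core 3 of the 10 gave at least as many genes (real count 2, highest other 2) and 2 gave at least as many lists (real count 13, highest other 14). In the periphery 1 gave as many lists (real count 14, highest other 11), while the count of genes was 0 in the real split, which 10 of the 10 must reach (highest other 0), so it decides nothing. Between compartments, core and periphery were exchanged within mice in 32 ways. The count of genes was reached by 1 of the 32, the real one (real count 2, highest other 0), and so was the count of lists (1 of the 32, real count 14, highest other 13). For the count of genes this argues against chance, but 1 of 32 is the lowest share these exchanges can give. That count was also 0 with mouse as a fixed block and with 5 of the 6 mice left out in turn. The count of lists does not decide, since it was chosen as a test after the result was seen and another exchange came within 1 list. It also rests on the preset correlation, as 1 list passed with an estimated one and 0 with fry.

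The p53 targets were lower in irradiated mice in both compartments, with a median of 0.48 from 0 over both, and the 10 splits are too few for a share under 0.05 (1 of 10 lay as far from 0, the real one, and the highest other was 0.29). Differences in hypoxia and proliferation between tumors are argued against, since with both scores as covariates the median nearer to 0 was -0.43 (core, adjusted p = 5.70e-16 with the preset correlation only). Gene dosage is argued against too, since the 10 nearest neighbours of each target had a median of 0.071 in the periphery and -0.02 in the core. A lower level of all moderately expressed genes could not be tested, since the normalization forces all arrays to the same distribution. In these values the list lay at percentile 0 of 10000 random lists matched on mean expression, of which 95% lay between -0.09 and 0.11 in the core. Genes of the random lists do not vary together as p53 targets do (estimated correlation 0.243), so this percentile is no measure of chance. Chance stays open, and so do, as untested, the irradiation itself and a difference in the age or stage of the tumors when the mice were killed, since survival times were not analysed here.

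Hypoxia genes were lower and cell cycle genes higher in the periphery, and chance is not excluded for either median. For hypoxia 2 of the 32 exchanges lay as far from 0 (real value 0.77 from 0, and 0.87 with control replicate 1 exchanged), and for the cell cycle also 2 (0.42, and 0.45 with the same mouse exchanged). Dilution of tumor RNA by host brain RNA would move tumor transcripts of the same level alike, so by itself it would not set these lists apart from them. Of 10000 random lists matched on mean expression, 0% lay as low as the hypoxia list and 0% as high as the cell cycle list (95% lay between -0.05 and 0.09 for each). The normalization holds random lists near 0 in any case, and their genes do not vary together as list genes do. These shares thus measure neither chance nor the amount of dilution. A difference carried by 1 mouse is argued against by the hypoxia median nearest to 0 with a mouse left out, -0.49 (without irradiated replicate 3). The cell cycle median was then also at its lowest, 0.25 against 0.42 with all mice, so that this mouse, with the widest differences, carried part of both. Beside chance, a difference between core and periphery as tissue stays open as untested, and control replicate 1, in which both scores went the other way, stays unexplained.

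Among 23 chromosomes, the genes of chromosome 18 stood highest in irradiated mice, with a median of 0.23 over both compartments and 82.8% of 99 genes with a mean above 6 lying above 0, ahead of chromosome 13 at 0.17. The 10 splits are too few for a share under 0.05, and 2 gave a chromosome median as large (real value 0.23, highest other 0.24). A trend with gene length is argued against, since genes of the same length on other chromosomes had a median of 0.037 (95% of draws between -0.02 and 0.09). Gene dosage of individual tumors may account for it: 2 of the 3 irradiated mice lay above every control mouse in both compartments, irradiated replicate 3 at 0.25 and 0.25 and irradiated replicate 1 at 0.10 and 0.20, while irradiated replicate 2 lay at 0.01 and -0.09 and control replicates 3, 2 and 1 at -0.15, -0.24 and -0.09 in the core and at -0.03, -0.21 and -0.09 in the periphery. Irradiated replicate 2 thus lay above the controls in the core and among them in the periphery. Copy number was not measured here, and an effect of irradiation stays open as untested.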
